A study of Mus musculus with 8 samples.

How the data were processed

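The data were bulk RNA sequencing libraries from whole mouse kidneys, 4 from animals labelled Cre-positive and 4 from animals labelled Cre-negative, all with floxed Hnf1b alleles and all given tamoxifen. Per the labels' protocols, RNA was extracted from frozen kidneys with a column kit, libraries were made with the Ovation Universal RNA-Seq System, and 100-base paired-end reads were sequenced on a NovaSeq instrument, with 50 M (M, 1000000) pairs stated for each library. The authors deposited whole-number read counts per Ensembl gene, 1 column for each library, with no normalization applied. Per the submitters' processing notes, HISAT2 (version not given in the sources used here) and HTSeq 0.13.5 were used with the GRCm38.p6 mouse build. The annotation release, the strand setting and any read filter are not given in the sources used here. The table held 48526 gene identifiers and no summary lines of unassigned reads. Of these, 48144 matched GENCODE release M21 for GRCm38, from which symbols, coordinates and exon overlaps were taken, and 382 did not match. A further 7392 of the 55536 genes of that release were not analysed here.

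Each column was assigned to an animal because its name stands in the title of 1 sample. Groups came from the genotype in the labels. Each title ends in a number of its own, read here as a mouse number, so the 8 libraries were treated as 8 animals. Replicate numbers were given in the order of the samples and pair nothing. A further number in the titles is 2, 3, 6 and 7 for the controls and 8, 10, 12 and 14 for the libraries labelled Cre-positive. It was read here as a library number, though the titles do not say what it counts. Any effect of library order, if it gives that order, cannot be told apart from the group.

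Total counts per library ran from 15.5 to 22.8 M. Pearson correlations of log2 CPM (counts scaled to a library total of 1000000, prior count 2) over genes were 0.979 to 0.992 between controls, 0.980 to 0.990 between kidneys labelled Cre-positive, and 0.932 to 0.967 between groups. Counts of paired libraries within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 7.21 to 50.2, so no library appeared to have been deposited 2 times. The biological coefficient of variation was 0.167. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

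Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with its expression filter by group, TMM factors and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Of the genes, 16178 passed the filter. Levels are TMM-scaled CPM as mean ± SD over 4 kidneys, and log2 fold changes are given ± standard error (SE), as the kidneys labelled Cre-positive against the controls. Hnf1b was also tested by an exact two-sided permutation of the 8 libraries. For a gene with no count in a group, the fold is a bound against a floor of 3 counts over that group. For a gene with 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. GC content and exon length were known for 99.7% of the tested genes.

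A set of 31 gene lists, from nephron segments and other cell types to pathways, was fixed before the data were examined. Each list with 3 or more tested members was tested with limma 3.58.1 camera on log2 CPM at a preset correlation of 0.01, adjusted over the lists, and its members were counted past the threshold over all genes and adjusted over the list alone. The rule for named genes was also fixed beforehand. It took Hnf1b and Cdh16, then, among genes past the threshold with a mean of at least 1 CPM and no overlap of the groups, the 8 largest rises and 8 largest falls, then the 4 rises and 4 falls with the smallest p. From each list it took up to 4 members with the smallest p past the threshold, or the most abundant member where none passed. Genes singled out by an outlying library or a closing test were added, and models without a given name were passed over. Other genes named in the text were chosen after their values were seen and are said to be so.

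Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, leaving out mitochondrially encoded genes, no count filter, a mean of at least 1 CPM, 1 surrogate variable from sva 3.50.0, edgeR's test against a 1.2-fold change, camera with an estimated correlation, fry, and leaving out each library. Offsets that remove each library's trends with GC content and exon length were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

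The gene test was tested on simulated counts with the means and library sizes of these 8 libraries, where 200 of 15999 genes were set to change. It recovered 18.2% of genes changed by 0.5 on the log2 scale, 61.5% of those changed by 1 and 98.5% of those changed by 2, and 5.65% of its calls were unchanged genes. Far more genes were called in the real counts, which loosens the threshold on the unadjusted p, so these shares need not hold there. Of the 31 lists, none was called in those counts, where no list was set to change as a whole. In a further simulation a list shifted by 0.5 was found with no other. Genes were simulated independently of each other, so this does not test camera on lists whose members vary together. The planned search for HNF1 binding motifs near transcription starts was left out because it needs genome sequence, which was not used here.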

Results

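Whole kidneys of 8 male mice aged 60 days were profiled by bulk RNA sequencing, to follow the earliest changes in expression after loss of HNF1B from tubular cells, ahead of a progressive kidney disease. HNF1B is a homeodomain transcription factor of the kidney tubule. All animals had floxed Hnf1b alleles and received tamoxifen (50 mg/ml per the labels) on 2 successive days. In 4 of them, labelled Cre-positive, a tamoxifen-inducible Cre was driven by the promoter of Cdh16, which encodes a cadherin of tubular epithelium. The other 4, labelled Cre-negative, served as controls. No group carried the Cre without floxed alleles, so effects of the Cre itself cannot be told apart from those of the deletion. Kidneys were taken 2 days after deletion. Total gene counts averaged 18.7 ± 3.38 M (M, 1000000 counts) in controls and 21.2 ± 1.34 M in kidneys labelled Cre-positive (SD, n = 4 each, exact permutation p = 0.314). TMM scaling factors were 0.951 ± 0.0173 and 1.05 ± 0.0309 with no overlap of the groups (exact permutation p = 0.0286, adjusted p = 0.229 over 8 library measures). The nuclear RNA Malat1 measured 304 ± 161 and 614 ± 244 CPM (exact permutation p = 0.114, adjusted p = 0.305).

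Hnf1b transcripts were higher, not lower, in every kidney labelled Cre-positive. The 4 controls measured 369, 303, 250 and 225 CPM, and the 4 kidneys labelled Cre-positive 512, 473, 510 and 557 CPM. The group means were 287 ± 64.0 and 513 ± 34.5 CPM (SD, n = 4 each), a 1.79-fold difference (log2 fold change 0.84 ± 0.15 SE, edgeR adjusted p = 0.00252). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 animals allow. Hnf1b (ENSMUSG00000020679) lies on chromosome 11 from 83850063 to 83905819 of GRCm38, plus strand, with no annotated exon of another gene overlapping its own. Gene-level counts also take in exons outside the floxed part, which the labels do not name, so these values check nothing about the deletion itself. No fall of Hnf1b was seen that would bear out the knockout label. The groups are therefore named here by their labels, and every direction given below rests on those labels. Cdh16 (ENSMUSG00000031881, chromosome 8, 104601911 to 104624396) measured 978 ± 104 CPM in controls and 1143 ± 118 CPM in kidneys labelled Cre-positive, a difference that did not pass the threshold (log2 fold change 0.22 ± 0.10, adjusted p = 0.137) except without control 3 (0.30, adjusted p = 0.0499).

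**Figure D1:**
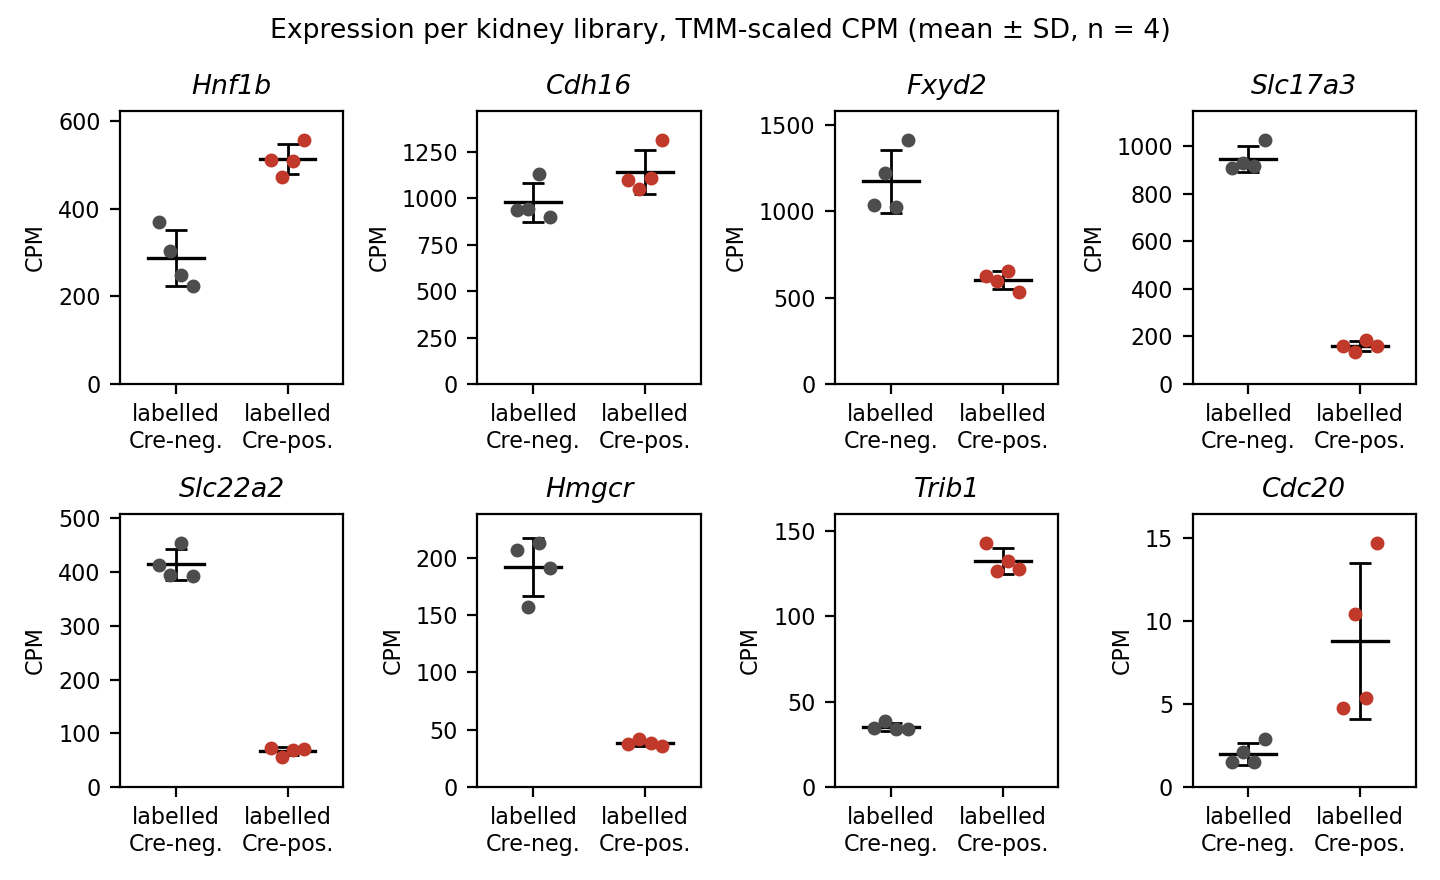
Expression of 8 genes in TMM-scaled CPM, with a point for each kidney library and the mean ± SD of 4 libraries per labelled group. Hnf1b is higher in the kidneys labelled Cre-positive, at 513 CPM on average against 287 CPM, while Slc17a3 is lower, at 160 CPM against 946 CPM.

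Large falls in the kidneys labelled Cre-positive included Cntnap5a, a contactin-associated protein, from 14.5 ± 2.59 to 0.0885 ± 0.0324 CPM (log2 fold change -7.24 ± 0.25), and the lens chaperone gene Cryaa (-6.55 ± 0.39), Lipo2 (-5.77 ± 0.39), Ctxn3 (-5.65 ± 0.22) and the adhesion receptor gene Adgrg4 (-5.61 ± 0.41). The smallest p among falls belonged to B3galt5, a galactosyltransferase gene on chromosome 16 (96235801 to 96319859), which fell from 91.7 ± 1.99 to 5.77 ± 0.580 CPM (log2 fold change -3.99 ± 0.10, adjusted p = 4.13e-08). Among falls that the naming rule had not already taken for their size, Tyw3 (-3.75 ± 0.10), the cytochrome P450 epoxygenase gene Cyp2j5 (-2.37 ± 0.08) and the aminoacylase gene Acy1 (-2.18 ± 0.08) followed. Cntnap5a had a smaller p than Acy1. Large rises included Chrna2, a nicotinic receptor subunit, from 0.466 ± 0.281 to 26.0 ± 3.91 CPM (log2 fold change 5.69 ± 0.29), with Lgi2 (4.25 ± 0.24), Klhl29 (3.70 ± 0.21) and the aldo-keto reductase gene Akr1c12 (2.59 ± 0.13). Trib1, which encodes a pseudokinase and lies on chromosome 15 (59648350 to 59657099), rose 3.75-fold, from 35.2 ± 2.45 to 132 ± 7.54 CPM (log2 fold change 1.91 ± 0.08, adjusted p = 5.33e-07).

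Some of the largest changes rested on counts near the floor. Ces1a had no count in any control and was at least 445-fold higher in kidneys labelled Cre-positive, although replicate 2 of that group held 0.755 CPM against 22.6 to 28.6 CPM in the others. Crisp1 had 4 counts over the controls and 61.8 CPM in the other group, and its log2 fold change of 9.95 ± 0.52 became 11.36 without control 4. Prss29 had 1 control count, for a ratio of 225 (95% counting interval 40.1 to 8927), and Cyp2d37-ps had 3, for a ratio of 64.4 (21.8 to 315). Tex21 had 3 counts over the kidneys labelled Cre-positive and was lower there by a ratio of 221 (75.1 to 1074). Sprn (6.39 ± 0.51), Muc13 (5.69 ± 0.66), Spink11 (5.54 ± 0.69), Ces1g (-6.83 ± 0.74) and Alkal2 (-5.90 ± 0.59) completed the set on the log2 scale. Values without 1 library lay over 1.5-fold away for several of them: 7.00 for Sprn without control 4, 6.27 for Spink11 without control 1, -7.89 for Ces1g without the kidney labelled Cre-positive 1 and -8.10 for Alkal2 without the kidney labelled Cre-positive 2. On the same scale Prss29 measured 7.32, but 9.08 without control 4 and 6.06 without the kidney labelled Cre-positive 2, Cyp2d37-ps 5.82, but 6.71 without control 1, and Tex21 -7.53, but -8.46 without the kidney labelled Cre-positive 2. Ces1a and Ces1g, Cyp2j5, Cyp2d37-ps and Akr1c12 belong to families of near-identical genes whose reads could have been split, and Tyw3, Cryaa, Alkal2, Sprn, Muc13 and Ces1a overlap a gene on the other strand, so these values are uncertain while the strand setting is unknown.

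Of 16178 genes tested, 1806 were higher and 2294 lower in the kidneys labelled Cre-positive (edgeR quasi-likelihood, adjusted p under 0.05), so that 56.0% of the calls were falls. With upper-quartile factors the split was 2328 higher and 1886 lower, or 44.8% falls. Changes of at least 2-fold numbered 469 rises and 664 falls. The values of the groups did not overlap for 1571 of the rises and 2131 of the falls, and 28.2% of all tested genes showed no overlap against 2.86% by chance. Leaving out control 2 lowered the rises to 1119. The first principal component held 58.1% of the variance and separated the groups. The number read as library order ran with the group, from 2 to 7 in controls and from 8 to 14 in the kidneys labelled Cre-positive.

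**Figure D2:**
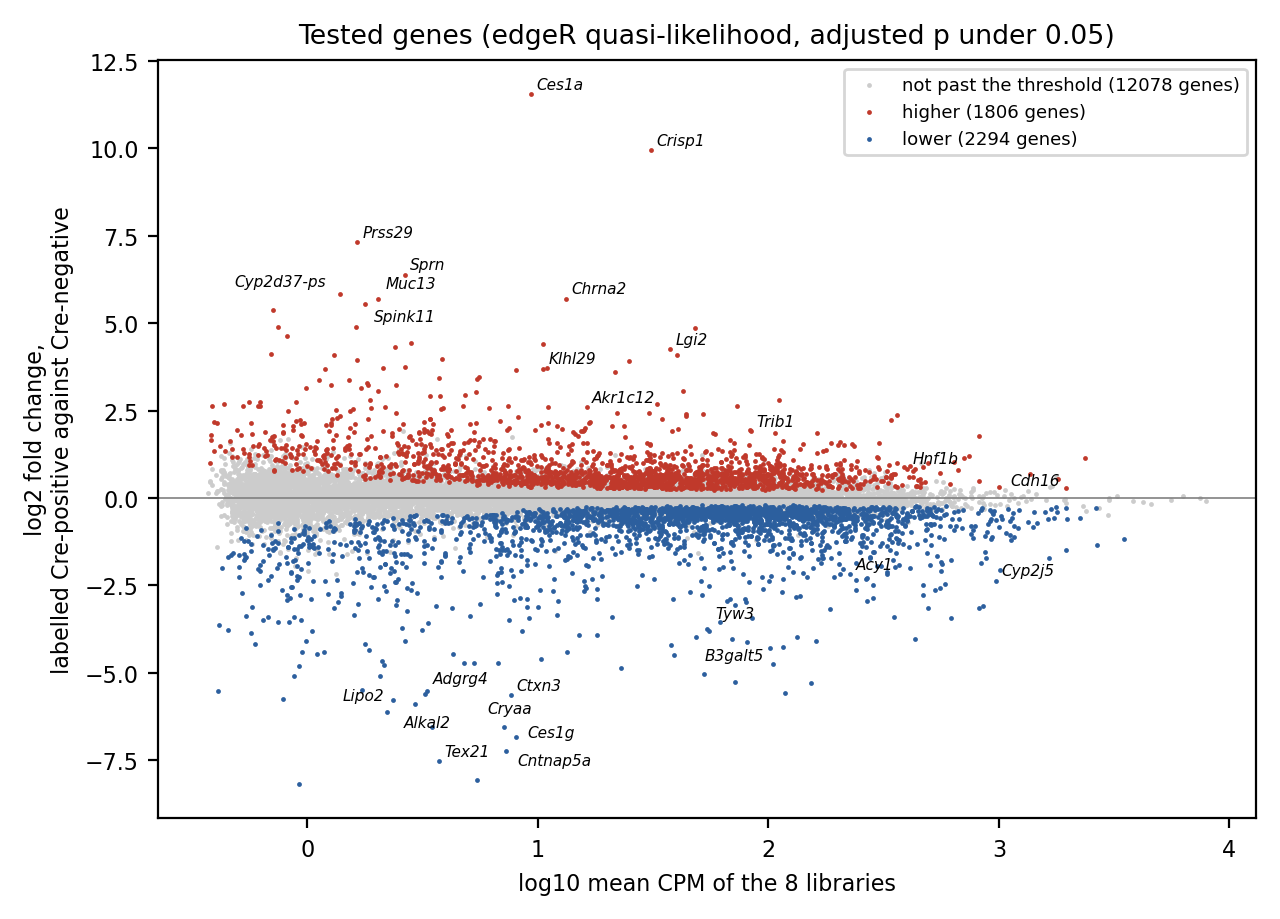
Log2 fold change of each tested gene against the log10 of its mean CPM over the 8 libraries, red for the 1806 genes higher in the kidneys labelled Cre-positive, blue for the 2294 lower and grey for the rest. Genes named by the fixed rule are marked.

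Among 17 genes known as HNF1B targets, 8 fell in the kidneys labelled Cre-positive and none rose, both over all genes and adjusted over the list alone. The bile acid receptor gene Nr1h4 fell 2.33-fold, from 300 ± 18.7 to 129 ± 4.99 CPM (log2 fold change -1.22 ± 0.08, adjusted p = 4.07e-06). Fxyd2, which encodes the gamma subunit of the sodium pump, fell from 1175 ± 183 to 602 ± 52.9 CPM (-0.96 ± 0.12), and Cltrn (-0.91 ± 0.13) and the organic anion transporter gene Slc22a6 (-0.86 ± 0.12) fell as well. Named after their values were seen, Umod, the uromodulin gene, fell by 0.25 (adjusted p = 0.0479), while the cystic disease genes Pkhd1 (-0.07, adjusted p = 0.823) and Pkd2 (-0.29, adjusted p = 0.188) did not pass. The list leaned down (median -0.25, camera adjusted p = 0.0244), but not with an estimated correlation (adjusted p = 0.445 with an estimated correlation). Its falls numbered 6 or 7 without any 1 library. There was 1 rise without control 3, that of Cdh16, which also stands in this list, and 1 without the kidney labelled Cre-positive 1. Its call also ended without control 3 (adjusted p = 0.0681) or without the kidney labelled Cre-positive 3 (adjusted p = 0.0723).

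Cystic kidney disease and ciliopathy genes numbered 30, of which 5 fell and 1 rose over all genes and adjusted over the list alone. Bbs7, a subunit of the ciliary BBSome, fell 2.29-fold (log2 fold change -1.19 ± 0.12), and the endoplasmic reticulum co-chaperone gene Dnajb11 (-0.56 ± 0.07) and the nephrocystin gene Nphp1 (-0.46 ± 0.08) fell. The member that rose was Hnf1b itself, and the list as a whole was not called (median -0.10, camera adjusted p = 0.124). It was called down without control 4 (adjusted p = 0.0272), without the kidney labelled Cre-positive 4 (adjusted p = 0.0329) and with GC and length trends removed (adjusted p = 0.00582).

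Markers of the thick ascending limb divided. Of 18, 7 fell and 2 rose in the kidneys labelled Cre-positive, over all genes and adjusted over the list alone. The paracellular magnesium channel gene Cldn16 fell from 9.91 ± 1.32 to 4.00 ± 0.936 CPM (log2 fold change -1.30 ± 0.18) and Tmem207 fell 3.39-fold (-1.76 ± 0.30), while the prostaglandin receptor gene Ptger3 (0.62 ± 0.08) and the sorting receptor gene Sorl1 (1.35 ± 0.22) rose. The segment's transporter gene Slc12a1, named after its value was seen, measured 0.05 (adjusted p = 0.791). The list was not called (median -0.04, and 0.01 with upper-quartile factors, camera adjusted p = 0.417), and its falls numbered 3 without control 2 and 4 without the kidney labelled Cre-positive 2.

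Farther along the nephron most markers did not pass. Of 18 distal convoluted and connecting tubule markers, 3 rose and 1 fell, or 2 and 1 adjusted over the list alone. Slc41a3 (0.79 ± 0.15) and the calcium channel gene Trpv5 (0.70 ± 0.16) rose and Tmem52b (-0.56 ± 0.13) fell. The median of -0.09 and the camera direction, up, differed in sign (adjusted p = 0.985). The falls numbered 2 without the kidney labelled Cre-positive 2, 3 or 4, and 3 with 1 surrogate variable or with GC and length trends removed. Of 15 principal cell markers, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone, with rises of the cortisol-inactivating enzyme gene Hsd11b2 (0.65 ± 0.10), Gata3 (0.55 ± 0.10) and Stc1 (1.30 ± 0.26). That list was called up (median 0.37, camera adjusted p = 0.0245; adjusted p = 0.409 with an estimated correlation), though not without control 3 (adjusted p = 0.0711), and its rises numbered 3 without the kidney labelled Cre-positive 2. Its fall was lost without control 1, control 2 or the kidney labelled Cre-positive 3. Of 17 intercalated cell markers, 4 rose and 1 fell, over all genes and adjusted over the list alone. Car2, a carbonic anhydrase gene, rose from 437 ± 30.3 to 973 ± 89.5 CPM (1.15 ± 0.09) and the anion exchanger gene Slc4a1 rose by 0.51 ± 0.12. This list was not called (camera adjusted p = 0.0641), but it was with fry (adjusted p = 0.0127), with GC and length trends removed (adjusted p = 0.0301), without control 1 (adjusted p = 0.0465) and without the kidney labelled Cre-positive 4 (adjusted p = 0.0329). Its rises numbered 2 without control 2, without control 4 or without the kidney labelled Cre-positive 1, and its fall was lost without control 2, control 4 or the kidney labelled Cre-positive 4.

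Proximal tubule markers formed the list with the smallest camera p. Of 28, 18 fell and 2 rose in the kidneys labelled Cre-positive, or 20 and 2 adjusted over the list alone. The urate and phosphate transporter gene Slc17a3 fell 5.92-fold, from 946 ± 54.3 to 160 ± 20.2 CPM (log2 fold change -2.56 ± 0.11, adjusted p = 3.55e-07). Slc22a30 fell 17.1-fold (-4.10 ± 0.26), Ttc36 3.77-fold (-1.91 ± 0.12) and the acyl-CoA synthetase gene Acsm2 from 4820 ± 156 to 2135 ± 166 CPM (-1.17 ± 0.08). Chosen after their values were seen, the sodium bicarbonate cotransporter gene Slc4a4 (0.67 ± 0.18) and the amino acid transporter gene Slc7a7 (0.90 ± 0.14) rose, and the endocytic receptor gene Lrp2 (0.21, adjusted p = 0.728) and the water channel gene Aqp1 (0.11, adjusted p = 0.377) did not pass. The list leaned down (median -0.72, camera adjusted p = 9.67e-08; adjusted p = 0.0984 with an estimated correlation). In the same kidneys the medians of endothelial and podocyte markers were 0.25 and 0.35. The rises numbered 1 without control 1, 2 or 4 or the kidney labelled Cre-positive 2.

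Carriers of organic ions, many of them proximal, gave a similar picture. Of 16, 9 fell and 2 rose, over all genes and adjusted over the list alone. The organic cation transporter gene Slc22a2 fell 6.20-fold, from 414 ± 28.3 to 66.8 ± 7.47 CPM (-2.63 ± 0.10), Slc22a13 18.4-fold (-4.20 ± 0.19), Slc22a19 9.06-fold (-3.18 ± 0.21) and Slc17a1 3.91-fold (-1.97 ± 0.12). The list was called down (median -0.60, camera adjusted p = 0.000506; adjusted p = 0.0984 with an estimated correlation). Slc22a6 stands in this list, in the proximal list and among the HNF1B targets. The rises numbered 1 without control 1, 2 or 4 or the kidney labelled Cre-positive 1, 2 or 4. Slc22a19 and Slc22a30 lie in a cluster of near-identical transporter genes, and their values are uncertain for that reason.

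Of 26 tubular transcription factor genes, 7 rose and 3 fell in the kidneys labelled Cre-positive, over all genes and adjusted over the list alone. Irx3 fell from 60.3 ± 5.82 to 25.5 ± 1.31 CPM (-1.24 ± 0.09) and Hnf4g, a nuclear receptor gene, fell from 12.3 ± 1.67 to 5.44 ± 0.639 CPM (-1.18 ± 0.14), while Gata3 and Tbx2 (0.46 ± 0.09) rose. Hnf4a, named after its value was seen, fell by 0.61 (adjusted p = 0.00615). The list was not called (median 0.29, camera adjusted p = 0.163), and its rises numbered 4 without the kidney labelled Cre-positive 1 and its falls 5 without the kidney labelled Cre-positive 4.

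Of 14 podocyte and parietal cell markers, 3 rose and 1 fell, over all genes and adjusted over the list alone. Mafb rose by 0.82 ± 0.14 and Pax8 by 0.52 ± 0.12, and the aminopeptidase gene Enpep fell (-1.13 ± 0.17). Pax8 also stands in the list of tubular transcription factors, so its rise need not come from these cells. Enpep was far more abundant in controls than Mafb (318 ± 70.8 against 22.1 ± 3.67 CPM), and which cells its fall came from was not tested. The list was called up (median 0.35, camera adjusted p = 0.0244; adjusted p = 0.509 with an estimated correlation), though not with fry (adjusted p = 0.0544) or without control 4 (adjusted p = 0.0537). Of 15 endothelial markers, 4 rose and none fell, over all genes and adjusted over the list alone, with Eng at 0.37 ± 0.11 and Tie1 at 0.34 ± 0.09 (camera adjusted p = 0.0267; adjusted p = 0.409 with an estimated correlation). None of these 4 calls held without control 2 or without the kidney labelled Cre-positive 1, 2 or 4, where Eng measured 0.34, 0.39, 0.35 and 0.32 and Tie1 0.31, 0.35, 0.33 and 0.29. Without control 1 or control 4 only 1 of the 4 held, with Eng at 0.36 and 0.33 and Tie1 at 0.35 and 0.29. The list was not called without control 2 (adjusted p = 0.0591), without the kidney labelled Cre-positive 2 (adjusted p = 0.0675) or with GC and length trends removed (adjusted p = 0.0676). Of 20 fibroblast, pericyte and matrix genes, 1 rose, or 0 adjusted over the list alone, and that member, Tgfb1 (0.35 ± 0.11), lost its call without control 1 (0.37), 2 (0.35) or 4 (0.28), without the kidney labelled Cre-positive 1 (0.35), 2 (0.39), 3 (0.37) or 4 (0.31) and with no count filter (0.37). The fibroblast list was not called (camera adjusted p = 0.181). Of 13 immune cell markers none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.520), and the most abundant, Cd74, measured 274 ± 210 CPM in controls and 266 ± 45.3 CPM in kidneys labelled Cre-positive. Control 4 held 588 CPM of Cd74, and without it the gene was higher in the kidneys labelled Cre-positive (0.65, adjusted p = 0.0171). Without control 2, 1 immune marker fell. Of 6 red blood cell genes 1 rose, Slc4a1, which intercalated cells also express (median -0.28 against a camera direction of up, adjusted p = 0.664), and of 7 adipose and adrenal genes 1 rose, the lipid droplet gene Plin4 (2.44 ± 0.944 to 7.54 ± 2.45 CPM, camera adjusted p = 0.181). Both counts were the same adjusted over the list alone.

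Genes of tubular injury were not called as a group. Of 23, 5 rose and 3 fell in the kidneys labelled Cre-positive, over all genes and adjusted over the list alone (camera adjusted p = 0.400). The ceruloplasmin gene Cp rose 2.61-fold (1.38 ± 0.10), and the growth factor gene Hbegf (-1.07 ± 0.11) and the receptor gene Tnfrsf12a (-0.72 ± 0.12) fell. Havcr1, which encodes the injury marker KIM-1, was high in controls, at 231 ± 163 CPM, and fell to 4.82 ± 3.96 CPM (log2 fold change -5.58 ± 0.96, adjusted p = 0.00252). Among the controls Havcr1 ranged from 18.3 CPM in control 1 to 416 CPM in control 4. The rises numbered 3 without control 1, control 2 or the kidney labelled Cre-positive 1.

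Most cell cycle genes rose. Of 23, 17 rose and none fell, over all genes and adjusted over the list alone (median log2 fold change 1.25, camera adjusted p = 3.06e-07; adjusted p = 0.409 with an estimated correlation). The replication licensing gene Cdt1 rose 2.36-fold, from 6.13 ± 0.544 to 14.5 ± 2.83 CPM (1.24 ± 0.15), the mitotic activator gene Cdc20 4.46-fold, from 2.00 ± 0.666 to 8.80 ± 4.69 CPM (2.16 ± 0.40), and the helicase subunit genes Mcm3 (0.78 ± 0.14) and Mcm6 (1.28 ± 0.24) rose. Named after their values were seen, the S-phase genes Pcna (0.10, adjusted p = 0.584) and Rrm2 (0.41, adjusted p = 0.171) did not pass. Of 20 p53 and DNA damage genes, 5 rose and 2 fell, or 8 and 2 adjusted over the list alone. Gdf15, a stress-induced cytokine gene, rose 4.14-fold (2.05 ± 0.21) and Psrc1 rose by 2.20 ± 0.39, while Rrm2b (-0.61 ± 0.11) and Ei24 (-0.49 ± 0.09) fell. This list was called up (median 0.29, camera adjusted p = 0.0267; adjusted p = 0.409 with an estimated correlation), but not without control 3 (adjusted p = 0.0538), without the kidney labelled Cre-positive 3 (adjusted p = 0.0723) or with a mean of at least 1 CPM (adjusted p = 0.0518). Its rises numbered 3 without control 1. Of 20 immediate early genes, 7 rose and none fell, or 8 and 0 adjusted over the list alone, among them Fosl2, from 16.6 ± 3.59 to 64.8 ± 10.2 CPM (1.96 ± 0.17), Myc (2.06 ± 0.22), Jun (1.02 ± 0.14) and Klf4 (0.83 ± 0.10). It was called up (median 0.52, camera adjusted p = 0.000173; adjusted p = 0.409 with an estimated correlation).

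Many cholesterol synthesis genes were lower in the kidneys labelled Cre-positive. Of 24 synthesis and uptake genes, 13 fell and 2 rose, over all genes and adjusted over the list alone. Hmgcr, the rate-limiting enzyme of the pathway, fell 4.99-fold, from 192 ± 25.2 to 38.5 ± 2.45 CPM (-2.32 ± 0.11, adjusted p = 9.62e-07). Cyp51 fell 8.93-fold (-3.16 ± 0.21), Mvd 5.69-fold (-2.51 ± 0.10) and Hmgcs1 3.55-fold (-1.83 ± 0.11). Named after their values were seen, the uptake genes Ldlr (0.28, adjusted p = 0.172) and Pcsk9 (0.43, adjusted p = 0.188) did not pass. The rises numbered 1 without control 1 or control 2. The list was called down (median -0.41, camera adjusted p = 0.000173; adjusted p = 0.409 with an estimated correlation).

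Of 20 fatty acid oxidation genes, 7 rose and 3 fell, or 9 and 4 adjusted over the list alone, and the list was called by fry (adjusted p = 0.0116) but not by camera (adjusted p = 0.0876). The ketogenic enzyme gene Hmgcs2 rose 5.28-fold (2.40 ± 0.36) and Acaa2 (0.74 ± 0.09) and Hadha (0.49 ± 0.09) rose, whereas the medium-chain dehydrogenase gene Acadm fell (-0.71 ± 0.10). The falls numbered 1 without the kidney labelled Cre-positive 1. Of 25 nuclear oxidative phosphorylation genes, 14 fell and none rose, or 20 and 0 adjusted over the list alone. The falls were small, with Sdhb at -0.54 ± 0.10, Ndufb3 at -0.56 ± 0.14 and Uqcrfs1 at -0.43 ± 0.09 (median -0.32, camera adjusted p = 6.15e-05; adjusted p = 0.472 with an estimated correlation). They numbered 7 with upper-quartile factors, 8 with no count filter, 4 without control 2 or the kidney labelled Cre-positive 1 or 2, 6 without the kidney labelled Cre-positive 4 and 7 without control 4. Of 13 mitochondrially encoded genes, 2 rose and 1 fell, over all genes and adjusted over the list alone (median -0.02 against a camera direction of up, adjusted p = 0.567). Those 3, mt-Co3, mt-Atp8 and mt-Co2, lie in parts of the mitochondrial genome that have near-identical nuclear copies or overlapping genes, so their values are uncertain. The call of mt-Co2 (-0.80 ± 0.25) ended without control 2 (-0.75), 3 (-0.85) or 4 (-0.59) or the kidney labelled Cre-positive 1 (-0.80), 2 (-0.80) or 3 (-0.70). It also ended with limma-voom (adjusted p = 0.0645), with 1 surrogate variable (0.0565) and with GC and length trends removed (-0.45, adjusted p = 0.183). The call of mt-Atp8 (1.78 ± 0.57, and 2.70 without control 2) ended without control 1 (1.54), 3 (adjusted p = 0.0931) or 4 (1.65) or the kidney labelled Cre-positive 2 (1.78) or 4 (1.39), and with 1 surrogate variable (adjusted p = 0.0669). Of 19 unfolded protein response genes, 8 fell and 1 rose, or 9 and 1 adjusted over the list alone. Edem1 (-1.14 ± 0.10), Pdia4 (-0.74 ± 0.10) and the chaperone gene Hspa5 (-0.48 ± 0.11) fell, and Chac1, a glutathione-degrading enzyme gene, rose from 0.962 ± 0.343 to 20.2 ± 12.7 CPM (4.39 ± 0.54). This list was not called (camera adjusted p = 0.0596), but it was with fry (adjusted p = 0.0409), with upper-quartile factors (adjusted p = 0.0472), with a mean of at least 1 CPM (adjusted p = 0.0362) and without control 1 (0.0362), control 2 (0.0347) or the kidney labelled Cre-positive 1 (0.0454). Its falls numbered 5 without the kidney labelled Cre-positive 1 and 4 without the kidney labelled Cre-positive 2. Of 23 ribosomal protein genes none passed, over all genes or adjusted over the list alone, and the most abundant, Rps3, measured -0.20 ± 0.18 (camera adjusted p = 0.172). That list was called down without control 3 (adjusted p = 0.0237).

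Of 13 Notch pathway genes, 5 rose and none fell, or 6 and 0 adjusted over the list alone. The effector gene Hes1 rose from 24.3 ± 4.14 to 47.3 ± 5.71 CPM (0.96 ± 0.14) and the ligand gene Jag2 rose by 0.51 ± 0.13, though its call ended with GC and length trends removed (0.26, adjusted p = 0.116). Notch genes were called up as a list (median 0.51, camera adjusted p = 0.00187; adjusted p = 0.409 with an estimated correlation). The rises numbered 2 without control 1 or control 2 and 3 without control 4 or the kidney labelled Cre-positive 1, 2 or 4. Of 16 TGF-beta targets and regulators of epithelial-mesenchymal transition, 6 rose and 1 fell, over all genes and adjusted over the list alone. The N-cadherin gene Cdh2 (1.07 ± 0.20), Smad6 (0.71 ± 0.13) and Serpine1 (0.71 ± 0.15) rose and Itgb6 (-1.19 ± 0.24) fell. The list was called up (median 0.18, camera adjusted p = 0.0409; adjusted p = 0.445 with an estimated correlation), but not without control 4 (adjusted p = 0.0823), without the kidney labelled Cre-positive 1 (0.0571) or 4 (0.0643) or with GC and length trends removed (0.0940). Its rises numbered 3 without control 1, 2 or 4 or the kidney labelled Cre-positive 1, 2 or 4. Of 14 Wnt target genes, 3 rose and 1, Sp5 (-0.63 ± 0.08), fell, over all genes and adjusted over the list alone. The cyclin gene Ccnd1 rose by 0.58 ± 0.15, and the list was not called (median 0.35, camera adjusted p = 0.0772) except with fry (adjusted p = 0.0211), without control 1 (0.0465) or without the kidney labelled Cre-positive 4 (0.0329). The rises numbered 1 without control 3, control 4 or the kidney labelled Cre-positive 1 or 2.

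Of 19 interferon response genes, 3 rose and none fell, over all genes and adjusted over the list alone. The transcription factor genes Irf9 (17.8 ± 1.75 to 35.8 ± 5.22 CPM) and Stat1 (1.06 ± 0.25) rose, with Irf9 overlapping Rnf31 and Stat1 overlapping Gm28177 on the same strand, which leaves both values uncertain. The list was not called (camera adjusted p = 0.102), but it was without control 4 (adjusted p = 0.0273) or the kidney labelled Cre-positive 4 (adjusted p = 0.00737). Of 14 glucocorticoid and fasting response genes, 7 rose and none fell, or 9 and 0 adjusted over the list alone. Angptl4, a lipoprotein lipase inhibitor gene, rose 2.01-fold, from 74.0 ± 21.6 to 149 ± 16.3 CPM (1.01 ± 0.19), and Igfbp1 (0.78 ± 0.18) and Fam107a (0.43 ± 0.08) rose (list median 0.59, camera adjusted p = 0.00187; adjusted p = 0.0984 with an estimated correlation). The rises numbered 4 without control 1 or control 2. Of 17 circadian clock genes, 2 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.256). Bhlhe41 measured 0.89 ± 0.23, a call that ended without control 1 (0.84, adjusted p = 0.0512) or control 2 (0.79, adjusted p = 0.0582). No rise was left in that list without either of those controls, and 4 were found with upper-quartile factors or without control 3 or the kidney labelled Cre-positive 3, and 1 without control 4 or the kidney labelled Cre-positive 2 or 4. The fall was lost without control 1, 2 or 3 or the kidney labelled Cre-positive 1, 2 or 3.

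**Figure D3:**
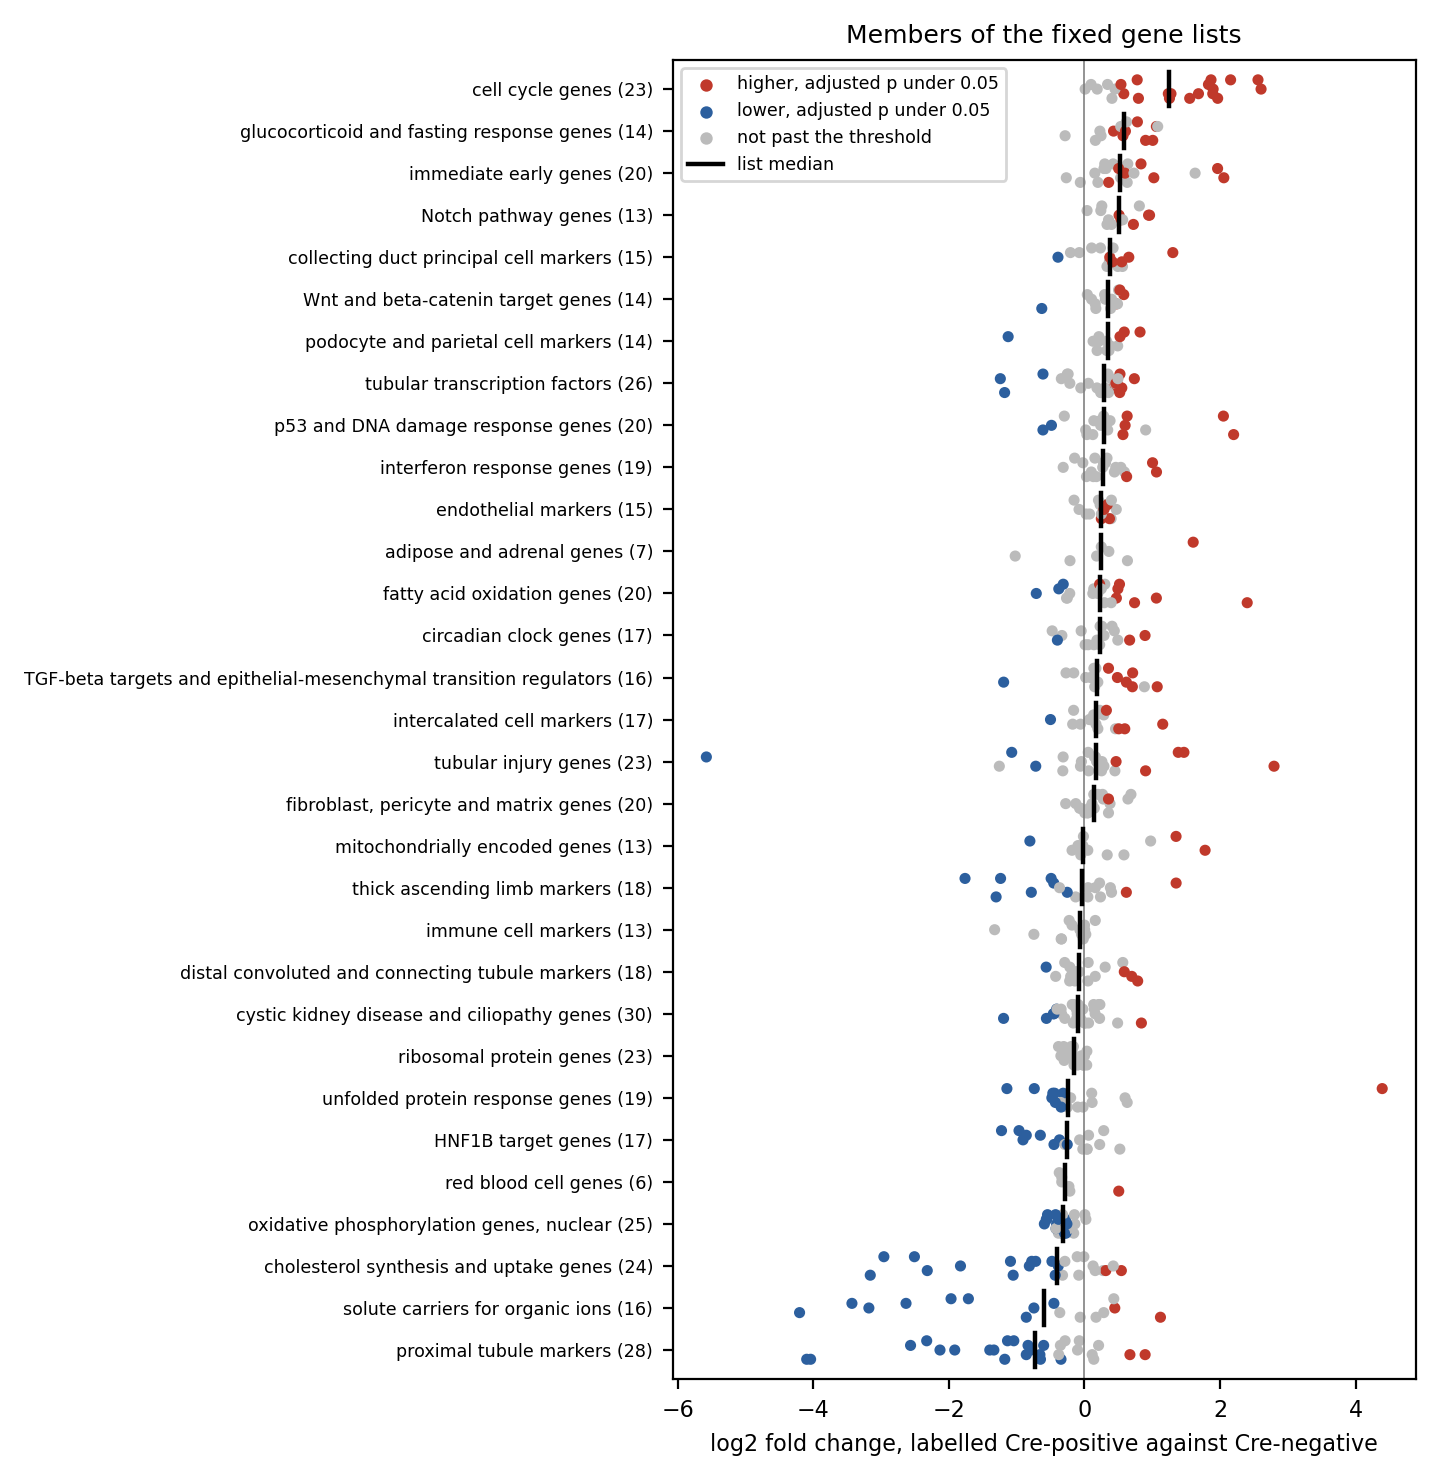
Log2 fold change of each tested member of the 31 fixed lists, with the number tested in brackets, red or blue where the gene passed the threshold and a black bar at the list median. Cell cycle genes have the highest median, 1.25, and proximal tubule markers the lowest, -0.72, in the kidneys labelled Cre-positive.

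Camera called 14 of the 31 lists, 9 up and 5 down, and none with an estimated correlation, where the lowest adjusted p was 0.0984. By fry, which asks whether a list's genes move on balance in 1 direction, 17 were called. Genes of several named lists overlap another annotated gene on the other strand. Among them are Sorl1, Gata3, Stc1, Ttc36, Pax8, Eng, Cp, Cdc20, Rrm2b, Ei24, Jun, Hmgcs1, Cyp51, Ccnd1, Hadha, Bhlhe41, Irx3 and Plin4. Wnk4, Axin2, Dll1, Ndufa2, Cry2, Tef and Cdkn1a do so too, with Pkhd1, Umod and Slc7a7 among those chosen after their values were seen. The values of all these genes are uncertain for as long as the strand setting of the counting is unknown. Gata3 also overlaps a gene on its own strand. With 1 surrogate variable more members passed in several lists: 9 principal cell, 9 p53, 8 Notch, 7 endothelial and 5 podocyte genes were higher, and 12 cystic disease and 6 fatty acid oxidation genes lower. With GC and length trends removed 8 principal cell genes and 1 Wnt target were higher and 10 cystic disease genes lower. Tested against a 1.2-fold change, these genes named by the rule no longer passed: Wnk4, Scnn1b, Slc4a1, Rhbg, Aqp6, Pax8, Plce1, Tie1, Plvap, Eng, Tek, Tgfb1, Ccnd1, Rnf43, Axin2, Jag2, Dll1, Ifit2, Hspa5, Uqcrfs1, Ndufb3, Ndufa2, mt-Co2, mt-Atp8, Cry2, Tef, Fam107a and Cdkn1a.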

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

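A library was singled out here when it lay far from the other 3 of its labelled group by Dixon's test, which chance alone meets in about 1 of 20 groups. Of 269 groups of 4 examined, 16 did so (5.95%), 4 each in the kidneys labelled Cre-positive 2 and 4, 3 each in controls 2 and 3, 2 in control 4 and none elsewhere. No explanation was tested for any of them.

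Among controls, Cd74, which encodes the invariant chain of antigen presentation, stood at 588 CPM in control 4 against 154 to 198 CPM in the others. Control 4 also held 0.0690 CPM of Prss29 where the others held 0. In control 3, Edem1 measured 203 CPM (others 161 to 164), Dnajb11 149 CPM (139 to 140) and Acaa2 183 CPM (212 to 214). In control 2, Trib1 measured 38.9 CPM (33.7 to 34.3), Cp 85.7 CPM (102 to 105) and mt-Atp8 2.63 CPM (0.432 to 0.690).

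In the kidney labelled Cre-positive 2, Prss29 measured 8.96 CPM (others 1.23 to 1.58), Cyp51 138 CPM (82.5 to 89.7), Hnf4g 4.48 CPM (5.74 to 5.77) and Alkal2 0.330 CPM (0 to 0.0427). In the kidney labelled Cre-positive 4, Klhl29 measured 26.6 CPM (16.6 to 17.8) and the Wnt target Sp5 22.2 CPM (lowest of the others 19.8). Hemoglobin transcripts made up 0.0184% of that library (0.0111 to 0.0122%) and protein-coding genes 98.252% (98.1% in the others).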

How the results depend on the processing

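No paired analysis was possible because the labels give the groups no shared replicate numbers. The removal of GC and length trends was chosen only after the data were seen, and the search for HNF1 binding motifs was not run. Main counts of 1806 genes higher and 2294 lower became 2759 higher with 1 surrogate variable, and 843 higher and 1270 lower against a 1.2-fold change, which asks for more than any difference. Leaving out each library gave 1119 to 1988 higher and 1682 to 2395 lower, with fewer samples in each fit. Over 128 named genes, 2154 of the comparisons kept their side of the threshold, and their direction wherever the gene passed. A change of sign in a gene that passed in neither fit was not counted. Of the rest, 143 lost a call, 1 gained one (Cdh16, without control 3), and 1 turned. The gene that turned, Cd74, measured -0.04 in full and ranged from -0.24 to 0.65 with a library left out. Its highest value came without control 4 (adjusted p = 0.0171), and the cause was not tested. Hnf1b stayed higher under every alternative. For the lists, 385 comparisons kept their side, 29 lost a call and 20 gained one, and no called direction turned. Camera called 14 lists, 15 with upper-quartile factors, 12 to 17 with a library left out and 0 with an estimated correlation. That setting allows for members that vary together, but this cannot be the reason for every lost call. The glucocorticoid and organic ion lists had negative estimates (-0.0403 and -0.0298), below the preset value. Their camera adjusted p still rose to 0.0984. Simulated changes of 0.5 on the log2 scale were recovered in 18.2% of genes, but only 200 of 15999 genes changed there. With the 4100 calls of the real counts the threshold on the unadjusted p is looser, so that share does not carry over. Small differences that did not pass stay open.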

Other observations

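Gene families were grouped by the letters that open the symbol, and the genes named from them chosen, only after the gene results were seen. The Fisher tests on families treat genes as independent draws, so their p-values do not measure variation between animals. Of 302 tested genes with Slc symbols, mostly solute carriers, 69 fell and 57 rose in the kidneys labelled Cre-positive (one-sided Fisher test over 190 families, adjusted p = 0.00567 and 0.00892, the latter 0.0516 with upper-quartile factors). The transporter gene Slc22a22 fell from 202 ± 40.1 to 7.47 ± 1.27 CPM (SD, n = 4 each) and the taurine transporter gene Slc6a6 rose by 1.77 ± 0.17. Hydroxysteroid dehydrogenase genes fell in 7 of 14 and rose in 2 (adjusted p of the falls = 0.0355), with Hsd3b4 (-4.61 ± 0.35), Hsd17b2 (-4.42 ± 0.38) and Hsd11b1 (336 ± 33.5 to 73.7 ± 17.9 CPM) lower and Hsd11b2 higher. Claudin genes fell in 8 of 18 and rose in 1, Cldn4 (adjusted p of the falls = 0.0355), with falls of Cldn2 (-0.60 ± 0.09), Cldn10 (-1.24 ± 0.22) and Cldn16. Aldehyde dehydrogenase genes fell in 9 of 21 and rose in 2 (adjusted p of the falls = 0.0355), with Aldh3b3 at -3.56 ± 0.24, and Nat genes in 7 of 13 (adjusted p = 0.0339), with Nat8f1 at -2.80 ± 0.14, a gene with near-identical neighbours.

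Falls were also more frequent among Tmem genes than among the other tested genes (48 of 199, with 19 higher, Fisher adjusted p = 0.0112). Genes of mitochondrial import, Timm (8 of 14, adjusted p = 0.0138), mitochondrial ribosomal proteins, Mrps (11 of 30, adjusted p = 0.0355), and mostly respiratory complex I, Ndufa (7 of 14, adjusted p = 0.0355), passed as well. With upper-quartile factors these 3 did not (adjusted p = 0.0687, 1 and 0.988). Other mitochondrial families did not pass in the main fit: Mrpl, with falls in 15 of 50 (Fisher adjusted p = 0.0523), Ndufb, in 3 of 11 (0.733), and Cox, in 6 of 26 (0.733).

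Genes with Cyp symbols, cytochrome P450 genes and pseudogenes, went both ways, with 17 of 51 lower (adjusted p = 0.0205) and 15 higher (adjusted p = 0.0199, 0.0738 with upper-quartile factors). Cyp27b1, which makes active vitamin D, rose from 14.4 ± 4.37 to 73.6 ± 41.7 CPM (2.35 ± 0.42). Cyp2a5 rose (2.39 ± 0.14) and its near-identical neighbour Cyp2a4 fell, from 662 ± 69.9 to 165 ± 16.1 CPM, so reads may have moved between the 2 and both values are uncertain. No test of that was run. Kinesin genes rose in 12 of 32 and fell in 3 (adjusted p of the rises = 0.00909, 0.0696 with upper-quartile factors), with Kif20a at 1.93 ± 0.35 and Kif2c at 2.27 ± 0.49, while Kif20b fell from 103 ± 32.1 to 7.35 ± 1.35 CPM (-3.81 ± 0.24).

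Of the tests below, only the count of chance splits was set before the results were seen. Among 35 splits of the 8 libraries into 4 and 4, 1 reached the 4100 genes called, the labelled split itself, and the highest of the others called 2.

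Hnf1b rose by 0.84 ± 0.15 in the kidneys labelled Cre-positive. Exchanged labels are a possible cause. Of the 8 HNF1B targets past the threshold, 100% were lower in those kidneys, as loss of HNF1B would have targets that it activates. However, 9 of the 17 targets did not pass. Among these 9, Cdh16 measured 0.22 and passed as higher without control 3 (0.30, edgeR adjusted p = 0.0499). Proximal tubule markers also fell broadly, and Slc22a6 stands in both lists, so these falls cannot settle the labels. The median of 68 distal markers was 0.15 (quartiles -0.18 to 0.40), below 0.55, the Hnf1b value less 2 SE. A gain shared alike by all distal segments, with no other change in their markers, therefore could not carry the rise of Hnf1b alone. The segments moved differently, however. List medians ran from -0.09 for the distal convoluted and connecting tubule to 0.37 for principal cells. Expression of these markers may also have changed within their cells. A larger share of only some distal segments, or a larger distal share together with other changes, therefore stays open. Trends with GC and length could not carry the rise of Hnf1b, as it stayed at 0.82 ± 0.15 with them removed. A biological explanation, more transcription of the exons that remain, was not tested because no counts by exon were analysed here.

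Proximal tubule markers fell (18 of 28). A lower share of all these cells, acting alone, would move all markers alike, but their interquartile range was 9.25 times their median SE. A loss of only some of these cells, or a lower share together with other changes, would also spread the markers. A lower share as part of the cause therefore stays open. With GC and length trends removed 17 of the 18 falls stayed. Library order, as read from the titles, could play a part and cannot be told apart from the group. The lowest such number of the kidneys labelled Cre-positive was 8 and the highest of the controls 7. Altered expression within these cells remains a candidate explanation.

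Male-biased kidney genes, 11 collected after the results were seen, all fell, with a median of -2.05. Less androgen receptor mRNA would not explain it, as Ar measured 0.31 ± 0.25 (adjusted p = 0.392). Their quartiles (-3.41 to -1.16) lay below the first quartile of 23 other proximal tubule markers (-1.09, median -0.60, or -0.72 with the 5 shared genes), but a set collected after the results may favour large falls, so a fall shared with those markers stays open. A shift of the whole kidney to the female pattern could not be judged, as 66.7% of only 3 female-biased genes past the threshold were lower. Androgen level, which may matter here, was not measured.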
